A study of Rattus norvegicus with 4 samples.

How the data were processed

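Nuclei were isolated from rat orbitofrontal cortex, captured in droplets with 10x Genomics 3' chemistry (v3.1) and sequenced on a NovaSeq6000, per the labels' protocols. The deposited files hold, for each of 4 libraries, UMI counts per gene and barcode, and per the file headers and the submitters' processing notes the authors made these counts with Cell Ranger 7.0.0. The notes name the human build hg38, while all 25399 gene identifiers in the files are rat Ensembl identifiers; the rat build and annotation release are not given in the sources used here, so no coordinates are printed. The fewest UMIs in a deposited barcode were 500 in every library. The counts hold no normalization. Gene symbols are those the files pair with the identifiers, and 148 symbols are shared by 2 or more identifiers. Whether the authors' counting could split reads between near-identical genes, such as ribosomal protein genes and their copies, is not given in the sources used here, so values of such genes are uncertain. AC134224.3, a gene with a placeholder name, took 4.84%, 6.02%, 5.53% and 5.24% of the UMIs in METH replicates 1 and 2 and saline replicates 1 and 2.

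The files were read with Scanpy 1.11.5, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 in Python 3.11.15; figures were drawn with matplotlib 3.10.9. Barcodes with under 500 genes were left out (489, 357, 1552 and 264, in the order METH replicates 1 and 2, saline replicates 1 and 2), then those with over 5% mitochondrial UMIs (12, 11, 13 and 32). Scrublet's doublet scores were computed per library. Its automatic threshold marked 18 barcodes (0.095%) in saline replicate 1, so it had not worked there, against 5.44%, 4.46% and 4.37% in the other libraries. After this was seen, 1 rule was used for all libraries: the barcodes with the highest scores were taken as doublets, up to 0.8% per 1000 barcodes scored, which comes to 8.22%, 7.14%, 15.2% and 6.77%. Of the barcodes that passed the other filters, 832, 629, 2750 and 569 were removed in this way.

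Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were selected with the library as batch, and a graph of 20 neighbours over 30 principal components was clustered by the Leiden method at resolution 1 with seed 1, with no other integration of the libraries. A cluster took the name of the marker list with the highest score, the mean over its genes of the cluster's log expression, centred and scaled across clusters. A name needed a score of at least 0.4, a score of the next list of an unrelated type of at most 0.6 of it, at least 3 markers detected in 10% of its nuclei, and no more markers of another class than of its own among its 10 leading genes by fold, computed with 10 CPM added. The marker lists were fixed before the data were examined. The score of 0.4 and the counting of subclass markers as markers of their own class were set after seeing the data; the share of nuclei left unnamed is given per library with the results.

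For each class with at least 50 nuclei in every library, counts were summed per library, since nuclei are not replicates. METH was compared with saline, 2 libraries each, by the quasi-likelihood F test of edgeR 4.0.16 (two-sided, robust, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested in a class and calls at an adjusted p under 0.05. The SE of a log2 fold change was taken as its size over the square root of F. The same test was run on all nuclei kept and, with the library as a block, on the class-by-treatment term of inhibitory and excitatory neuron-like nuclei. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over all pairs of a class and a list; camera with an estimated correlation and fry were run beside it. Of 35 lists, 34 had enough members in at least 1 class. They cover neuronal activity, dopamine and other monoamine signalling, synapses, channels, neuropeptides, chromatin, mitochondria, ribosomes, stress, glucocorticoids, the clock, myelin, cholesterol, glia, inflammation, interferon and markers of 7 cell types, of striatal neurons and of blood. Some genes stand on more than 1 list, such as C1qa on both microglia lists. Levels are given as CPM, the count scaled to the library total. Class shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only.

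Named genes were chosen by a rule fixed before the data were examined: of the genes called, with both METH values on one side of both saline values and no placeholder name, up to 12 per direction in the neuronal classes and 6 in the others. Where no gene was called in a direction, the 3 with the smallest p were given as values. Members of the lists were named if called, and otherwise the 2 with the smallest p; Fos, Arc, Npas4, Drd1, Drd2, Bdnf and Fkbp5 were given in excitatory neuron-like nuclei whatever their result. AABR07043564.1, Nr4a2, Klf9, Mertk outside OPC-like nuclei, the genes counted per nucleus, the genes called by DESeq2 and those of the subclasses fall outside the rule and were chosen after their values were seen.

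Alternatives fixed before the data were examined were RLE size factors, no filter on low counts, the replicate number as a block, a fit that was not robust, leaving out each library in turn, at least 200 or 1000 genes per nucleus, at most 1% mitochondrial UMIs, doublets kept, the resolution doubled, equal nuclei per library, and DESeq2 1.42.0. Chosen after seeing the data were the fits without differentiating cells and with the endothelial-like cluster alone, shares without each library, shares after thinning all nuclei so that the excitatory neuron-like medians matched saline replicate 1, and the tests in subclasses. The last were repeated under the alternatives fixed before, except equal nuclei and DESeq2, where each library held at least 50 nuclei of the name. When 1 library is left out, the lone library of its group is assumed to vary like the other group.

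The procedure was tested on simulated data, with the real genes' means and library sizes and 200 genes changed, 67 each by 1.5-fold and 2-fold and 66 by 4-fold. At these folds it recovered 59.7%, 80.6% and 90.9% in excitatory neuron-like nuclei (15041 genes, 21 false calls), 55.2%, 73.1% and 93.9% in inhibitory neuron-like nuclei (11761 genes, 4), 25.4%, 59.7% and 92.4% in astrocyte-like nuclei (10069 genes, 10), and 11.9%, 47.8% and 87.9% in oligodendrocyte-like nuclei (9390 genes, 13). It recovered 34.3%, 67.2% and 87.9% in OPC-like nuclei (9751 genes, 9), 8.96%, 29.9% and 81.8% in microglia-like nuclei (7398 genes, 8), and 0%, 4.48% and 60.6% in vascular-like nuclei (6891 genes, 0). For all nuclei the shares were 46.3%, 79.1% and 93.9% (16242 genes, 33), and for the class-by-treatment term 32.8%, 58.2% and 93.9% (14964 genes, 9). Every recovered gene had the right direction, and in several classes false calls made up more than the 5% aimed at. A simulated list of 20 genes raised by 0.5 on the log2 scale was called by camera in all 7 classes with 0 or 1 of 100 unchanged lists called, while camera with an estimated correlation and fry called it in none and fry called 1 unchanged list in OPC-like nuclei. The genes were simulated independently of each other. Lists whose genes vary together between libraries were thus not covered, and the simulation cannot tell whether the preset correlation holds for them. Apart from the changed genes, all simulated libraries of a class had the same mean profile. A library that stands apart, as saline replicate 1 does, was not simulated, so the recovered shares may not hold for the real comparison.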

Results

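The orbitofrontal cortex, a prefrontal region involved in valuing rewards and in choosing between actions, was profiled by single-nucleus RNA sequencing in male Sprague-Dawley rats aged 8 weeks. One group had been given methamphetamine (METH), a stimulant that releases dopamine and other monoamines, at 1 mg/kg over 7 days, and the other group saline. The title of the series places the animals in a model of sensitization, the growing response to a repeated drug dose, and the comparison asks which cell types and genes differ after METH. Each group was represented by 2 libraries. Tissue came from 4 animals per group, but which animals entered which library is not given in the sources used here, so p-values measure only the spread between libraries, which may be partly technical.

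The files held 10275 barcodes for METH replicate 1, 8933 for METH replicate 2, 18958 for saline replicate 1 and 8467 for saline replicate 2. They carried 39552954, 37758602, 44034787 and 38811323 UMIs, the unique molecular identifiers that each count 1 captured transcript. After filtering, 8942, 7936, 14643 and 7602 nuclei remained, with medians of 2895.5, 2804, 1963 and 3521 UMIs and of 1687, 1635.5, 1271 and 1959.5 genes per nucleus. Saline replicate 1 stood apart from the other libraries, with the most nuclei and the fewest UMIs in each.

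The 39123 nuclei fell into 25 clusters, named by marker genes chosen before the data were examined. Excitatory neuron-like nuclei were the most numerous at 19094, followed by 4465 inhibitory neuron-like, 4025 astrocyte-like, 3518 oligodendrocyte-like, 2906 OPC-like (oligodendrocyte precursor), 1718 microglia-like and 986 vascular-like nuclei. The leading genes of the clusters included Otof and Cux2 for upper-layer neurons, Foxp2 and Syt6 for layer 6 corticothalamic neurons, Vip and Prox1 for Vip interneurons, Mog and Mobp for oligodendrocytes, Pdgfra and Vcan for OPCs, and Dock8, Inpp5d and Ctss for microglia. A further 161 nuclei led by Mrc1, F13a1 and Cd163 were perivascular macrophage-like, with 32, 43, 10 and 76 nuclei in the 4 libraries, too few for a test. In 3 clusters the markers did not settle a name. They held 201, 179, 1790 and 80 nuclei, or 2.25%, 2.26%, 12.2% and 1.05% of the nuclei kept, and most of those in saline replicate 1 belonged to a cluster led by Cga, Fth1, Id2, Jund and Egr1.

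Glial nuclei made up a larger share of the METH libraries than of the saline libraries on average, and excitatory neuron-like nuclei a smaller one. Oligodendrocyte-like nuclei were 12.5% (95% exact Clopper-Pearson interval 11.8 to 13.2) and 13.9% (13.1 to 14.6) in METH, against 3.54% (3.24 to 3.85) in saline replicate 1 and 10.3% (9.64 to 11.0) in saline replicate 2. Microglia-like nuclei were 5.74% (5.26 to 6.24) and 7.04% (6.49 to 7.63) in METH, against 1.05% (0.893 to 1.23) and 6.47% (5.93 to 7.05) in saline. Astrocyte-like nuclei averaged 12.5% ± 1.56 (SD, n = 2) in METH and 8.75% ± 0.255 in saline, and OPC-like nuclei 9.21% ± 0.441 and 6.75% ± 2.96. Excitatory neuron-like nuclei averaged 41.9% ± 3.14 and 52.3% ± 7.44, inhibitory neuron-like nuclei 11.5% ± 2.05 and 11.4% ± 0.300, and vascular-like nuclei 2.70% ± 1.17 and 2.99% ± 2.55. The intervals cover counting error only. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, so it could call no share different, and no other test of shares was run. After all nuclei were thinned to the depth of saline replicate 1, the METH minus saline difference was 0.150 percentage points for microglia-like nuclei (2.63 as deposited), 1.09 for oligodendrocyte-like (6.25), −3.15 for excitatory neuron-like (−10.4), 2.20 for inhibitory neuron-like (0.115) and −0.532 for vascular-like nuclei (−0.285). For astrocyte-like nuclei the thinned difference was 2.92 (3.70) and for OPC-like nuclei 2.10 (2.47). With at least 1000 genes per nucleus it was 0.959 for microglia-like, 1.85 for oligodendrocyte-like, 5.96 for astrocyte-like (3.70) and 2.30 for inhibitory neuron-like nuclei. For vascular-like nuclei it was −0.00483 with at least 200 genes and −0.125 with doublets kept. For inhibitory neuron-like nuclei it was 0.327 with doublets kept, 0.0672 with the resolution doubled and 0.212 with at most 1% mitochondrial UMIs. Without saline replicate 1, the METH minus saline difference was −0.0816 percentage points for microglia-like nuclei (2.63 with all libraries), 2.86 for oligodendrocyte-like nuclei (6.25), 0.374 for OPC-like nuclei (2.47), −5.14 for excitatory neuron-like nuclei (−10.4) and −2.09 for vascular-like nuclei (−0.285). Without saline replicate 2 it was 5.34 for microglia-like, 9.63 for oligodendrocyte-like, 4.56 for OPC-like, −15.7 for excitatory neuron-like and 1.52 for vascular-like nuclei. The difference for inhibitory neuron-like nuclei ran from −1.33 without METH replicate 1 to 1.56 without METH replicate 2 (0.115), with −0.0969 without saline replicate 1 and 0.327 without saline replicate 2. For vascular-like nuclei it was 0.540 without METH replicate 1 and −1.11 without METH replicate 2. For astrocyte-like nuclei it ran from 2.60 without METH replicate 2 to 4.81 without METH replicate 1.

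**Figure D1:**
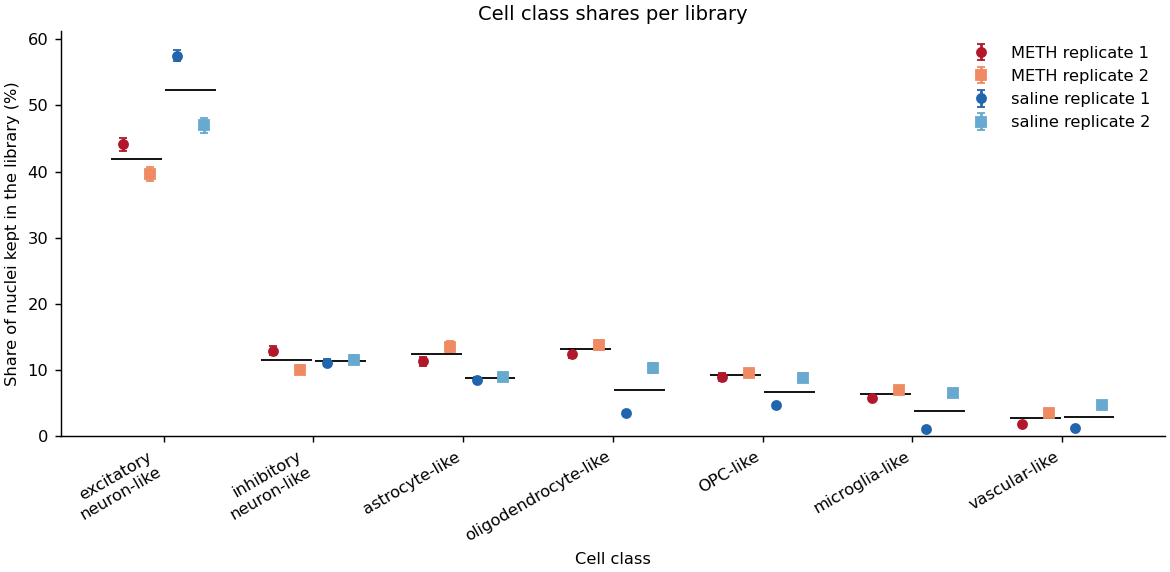
Share of nuclei in each cell class (%, vertical axis) for the 4 libraries, with 95% exact intervals as bars and the mean of each group as a black line. Saline replicate 1 lies apart for oligodendrocyte-like nuclei (3.54%) and microglia-like nuclei (1.05%), while the astrocyte-like shares of both METH libraries (11.4% and 13.6%) lie above both saline libraries (8.57% and 8.93%).

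In excitatory neuron-like nuclei, 2 of 15031 genes tested passed the threshold and both were higher in METH. Cst3 (ENSRNOG00000005195), which encodes cystatin C, a secreted inhibitor of cysteine proteases, rose from 79.1 ± 0.385 CPM (counts scaled to the library total; SD, n = 2) to 147 ± 16.5. Its log2 fold change was 0.89 (SE 0.0779; edgeR quasi-likelihood test, adjusted p = 0.00361), and both METH libraries lay above both saline libraries. AABR07043564.1, a gene with a placeholder name that was singled out after its values were seen, rose by 1.09 (SE 0.137, adjusted p = 0.0451), from 5.09 to 10.9 CPM. DESeq2 called these 2 and Tsga10ip, named for binding the testis protein Tsga10 and likewise singled out after its values were seen. By edgeR Tsga10ip was at 1.46 (SE 0.245, adjusted p = 0.879), with 9.17 and 15.4 CPM in METH against 4.52 and 4.41 in saline. Its adjusted p ran from 3.65e-11 without METH replicate 1 to 1 without saline replicate 1 over 15 alternatives, DESeq2 among them (1.72e-04). No gene fell. The lower genes with the smallest p were Fosl1, a Fos-family subunit of the AP-1 transcription factor (log2 −0.89, SE 0.182, adjusted p = 0.879), Tnfrsf19, a receptor of the tumour necrosis factor family (−0.47, SE 0.109), and Kcnv2, a modifier subunit of potassium channels (−2.35, SE 0.568), the last 2 at an adjusted p of 0.9996. Genes given whatever their result did not pass either. The activity-induced genes Fos, Arc and Npas4 were at log2 0.17 (SE 0.164), 0.11 (SE 0.095) and 0.15 (SE 0.184), the neurotrophin Bdnf at 0.04 (SE 0.0684), the dopamine receptors Drd1 and Drd2 at 0.34 (SE 0.427) and 0.16 (SE 0.204), and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 0.29 (SE 0.107). Nr4a2, an activity-regulated nuclear receptor on the immediate early gene list, was at −0.62 (SE 0.162, adjusted p = 0.9996). Nr4a2 is also on the list of claustrum neuron markers, and whether the share of such neurons set its value was not tested. Leaving out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 gave 63, 38, 0 and 3 genes. Over 15 alternatives the adjusted p of Cst3 ran from 1.28e-26 to 0.0825, above 0.05 without saline replicate 1, and that of AABR07043564.1 from 7.45e-05 to 0.303, above 0.05 in 5 of them, the fits without saline replicate 1 (0.303), without saline replicate 2 (0.177), not robust, with at least 1000 genes per nucleus and with equal numbers of nuclei.

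Among the gene lists chosen before the data were examined, 4 stood higher in excitatory neuron-like nuclei by camera, which sets a list against all other genes. Of 20 tested members of the activated microglia and inflammation list, 15 had positive fold changes (median log2 0.36, adjusted p = 3.68e-10). None passed over all genes, and 6 rose when adjusted over the list alone, led by C1qa, a chain of the complement protein C1q made by microglia (0.82, SE 0.14), and B2m, the light chain of class I antigen-presenting molecules (0.82, SE 0.143). The microglia marker list had a median of 0.47 over 12 members (adjusted p = 1.57e-06), with 0 past the threshold over all genes and 3 adjusted over the list alone, among them C1qb (0.68, SE 0.167). C1qa was counted at 0.057 and 0.0769 UMIs per excitatory neuron-like nucleus in METH and at 0.0179 and 0.0417 in saline, close to the 0.049, 0.0648, 0.0205 and 0.0342 in OPC-like nuclei and far below the 0.606, 0.703, 0.338 and 0.63 in microglia-like nuclei. The postsynaptic density list had a median of 0.07 and a mean of 0.03 over 25 members (adjusted p = 0.0202), with examples in the scaffold genes Dlg1 (0.12, SE 0.0561) and Dlgap4 (0.16, SE 0.0741). The voltage-gated channel list had a median of 0.05 over 36 members (adjusted p = 0.0297), with the potassium channel genes Kcnh5 (0.16, SE 0.0606) and Kcnh7 (0.16, SE 0.064) among those with the smallest p. In neither list did a member pass, over all genes or adjusted over the list alone. Kcnh5 is also a marker of L4/5 IT-like nuclei (neurons of those cortical layers). These were 26.8% and 29.1% of the class in METH and 26.1% and 25.2% in saline replicates 1 and 2. L2/3 IT-like nuclei were 23.7% and 31.5% in METH and 26.3% and 25.1% in saline. Whether such shares set the values of these lists was not tested. All 4 list calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). In the simulation this version called no raised list in any class, so its losses, here and below, do not decide on the calls. The microglia marker call was also lost without saline replicate 2 (median 0.23), that of the postsynaptic density list without METH replicate 1 (0.05) or saline replicate 1 (0.06) or with equal numbers of nuclei (0.06). That of the voltage-gated channels was lost without METH replicate 1 (0.02) or saline replicate 1 (0.04) or with at least 1000 genes per nucleus (0.05). Over the alternatives the medians ran from 0.21 to 0.39 for the activated microglia list and from 0.23 to 0.64 for the microglia markers.

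In inhibitory neuron-like nuclei 2 of 11842 genes passed, both higher in METH. Cst3 rose from 124 ± 0.712 to 239 ± 10.8 CPM (SD, n = 2), a log2 change of 0.95 (SE 0.0763, adjusted p = 1.06e-06), and stayed past the threshold under all 15 alternatives (highest adjusted p 0.0051). Mybpc1 (ENSRNOG00000056493), a myosin-binding protein known from the muscle sarcomere, rose by 0.72 (SE 0.109, adjusted p = 0.0109), from 52 ± 0.894 to 85.5 ± 7.21 CPM. Mybpc1 was among the leading genes of the Pvalb-like cluster, which held 35.2%, 27.6%, 33.2% and 32.6% of the inhibitory neuron-like nuclei in METH replicates 1 and 2 and saline replicates 1 and 2. The lower genes with the smallest p were Rspo2, a secreted enhancer of Wnt signalling (−0.35, SE 0.0887), Arhgap31, a GTPase-activating protein (−1.24, SE 0.325), and Chd5, a chromatin remodeller (−0.28, SE 0.075), none of which passed (adjusted p = 0.9999 each). Fits that left out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 called 34, 8, 2 and 1 genes. The adjusted p of Mybpc1 ran from 1.12e-06 to 0.317 over 15 alternatives and was above 0.05 without saline replicate 1 (0.317), without saline replicate 2 (0.225), by DESeq2 (0.21) and with equal numbers of nuclei (0.134).

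Lists moved both ways in inhibitory neuron-like nuclei. The mitochondrially encoded genes had a median of −0.27 over 13 members (adjusted p = 0.00611), 10 of them negative, with Mt-co2, a subunit of cytochrome oxidase, at −0.40 (SE 0.185) and Mt-nd3, a subunit of complex I, at −0.38 (SE 0.215). The other monoamine receptors had a median of 0.15 with all 6 tested members positive (adjusted p = 0.0149), among them the serotonin receptors Htr2c (0.18, SE 0.0786) and Htr4 (0.39, SE 0.172). No member of either list passed, over all genes or adjusted over the list alone. Without METH replicate 2 the median was 0.01 for the mitochondrial genes and 0.0066 for the monoamine receptors, and the direction of both tests turned. The mitochondrial call was also lost without saline replicate 2 (−0.17), with at least 1000 genes per nucleus (−0.22) and with at most 1% mitochondrial UMIs (−0.11). The monoamine receptor call was lost without saline replicate 1 (0.08), without a filter on low counts (0.09) and with equal numbers of nuclei (0.11). The activated microglia and inflammation list had a median of 0.28 over 15 members (adjusted p = 0.00412), with 0 past the threshold over all genes and 2 adjusted over the list alone, C1qb (1.16, SE 0.288) and C1qa (0.81, SE 0.231). C1qa stood at 0.0588, 0.0691, 0.0178 and 0.0398 UMIs per nucleus. The call was lost without a filter on low counts (median 0.05), and over the alternatives the median ran from 0.05 to 0.39. All 3 calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each).

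In astrocyte-like nuclei 1 of 10093 genes passed. Smarcc1 (ENSRNOG00000020804), which encodes a core subunit of the SWI/SNF (BAF) chromatin remodelling complexes, rose by 0.83 (SE 0.107, adjusted p = 0.0127), from 221 ± 6.65 to 392 ± 12.9 CPM (SD, n = 2). It stayed past the threshold under all 15 alternatives (highest adjusted p 0.0494). In excitatory neuron-like nuclei Smarcc1 stood at 131 and 121 CPM in METH and 124 and 124 CPM in saline, and in OPC-like nuclei at 245, 244, 213 and 226 CPM; whether its change differs between classes was not tested. Cst3 had a log2 change of 0.62 in astrocyte-like nuclei (SE 0.0999, adjusted p = 0.0772). The lower genes with the smallest p were Lrrc4c, an adhesion protein that binds netrin-G (−0.46, SE 0.109), Cpne8, a calcium-dependent membrane-binding protein (−1.12, SE 0.27), and Tmem144 (−0.77, SE 0.199), none of which passed (adjusted p = 0.9985 each). Without METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 the count of genes was 38, 2, 12 and 128.

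Mitochondrially encoded genes were lower in the METH astrocyte-like nuclei, with all 12 tested members negative and a median of −0.47 (adjusted p = 2.34e-06). Mt-nd1 and Mt-nd4, subunits of complex I, were both at −0.68 (SE 0.247 and 0.268). Over all nuclei kept, the median mitochondrial share of UMIs was 0.0788% and 0.0525% in METH replicates 1 and 2. It was 0.0627% and 0.0575% in saline replicates 1 and 2, so the METH libraries lay on both sides of saline. Whether METH or the preparation of the libraries set the mitochondrial changes, in this or any other class, was not tested. Lists of other cell types stood higher. The activated microglia and inflammation list had a median of 0.57 over 10 members (adjusted p = 3.32e-06), with B2m (0.74, SE 0.154) and C1qa (0.74, SE 0.229) at the smallest p. The myelin list had a median of 0.25 over 11 members (adjusted p = 0.0111) and the oligodendrocyte marker list 0.25 over 7 (adjusted p = 0.048), with the myelin proteins Mal (0.70, SE 0.22), Cldn11 (0.75, SE 0.363) and Mag (0.70, SE 0.354) as examples. No member of these 4 lists passed over all genes, and adjusted over the list alone 2 of the activated microglia list rose and 0 of the other lists. C1qa was counted at 0.0571, 0.0771, 0.0255 and 0.0398 UMIs per astrocyte-like nucleus in METH replicates 1 and 2 and saline replicates 1 and 2. All 4 calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). The mitochondrial call was also lost without METH replicate 2 (median −0.14), the myelin call without METH replicate 1 (0.0076) or saline replicate 2 (0.11) or with at least 1000 genes per nucleus (0.31). The oligodendrocyte marker call was lost without METH replicate 1 (0.30) or saline replicate 2 (0.13), without a filter on low counts (0.26), with at least 200 genes (0.24) or with equal numbers of nuclei (0.22). Over the alternatives the medians ran from −0.84 to −0.14 for the mitochondrial genes, from 0.33 to 0.60 for the activated microglia list, from 0.0076 to 0.39 for myelin and from 0.13 to 0.61 for the oligodendrocyte markers.

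In oligodendrocyte-like nuclei 2 of 9427 genes passed, both higher in METH. Sgk1 (ENSRNOG00000011815), the serum- and glucocorticoid-regulated kinase, rose by 1.13 (SE 0.163, adjusted p = 0.0268), from 119 ± 26.5 to 268 ± 1.13 CPM (SD, n = 2). Cst3 rose by 1.24 (SE 0.184, adjusted p = 0.0405), from 288 ± 94.7 to 700 ± 24.8 CPM. Sgk1 stood at 116 and 122 CPM in METH and at 120 and 123 CPM in saline in excitatory neuron-like nuclei, and at 251, 256, 251 and 246 CPM in inhibitory neuron-like nuclei; whether its change differs between classes was not tested. The lower genes with the smallest p were Grm7, a metabotropic glutamate receptor (−0.78, SE 0.144, adjusted p = 0.143), Vcan, a matrix proteoglycan of OPCs (−0.76, SE 0.163, adjusted p = 0.548), and Nlgn3, a synaptic adhesion protein (−1.34, SE 0.362, adjusted p = 0.9997). Differentiating cells, the cluster led by Bcas1, Enpp6 and Tns3, were 18.7% of this class in saline replicate 1 and 7.07%, 6.73% and 8.29% in METH replicates 1 and 2 and saline replicate 2. With the resolution doubled, the class held 548 nuclei instead of 518 in saline replicate 1. It stayed at 1117, 1099 and 784 nuclei in METH replicates 1 and 2 and saline replicate 2. The counts without METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 were 20, 3, 11 and 148, and both genes lost their calls with at least 200 or at least 1000 genes per nucleus, with doublets kept or with the resolution doubled, and Cst3 also with equal numbers of nuclei. Over 16 alternatives the adjusted p ran from 3.41e-09 to 1 for Sgk1 and from 1.49e-14 to 1 for Cst3.

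**Figure D2:**
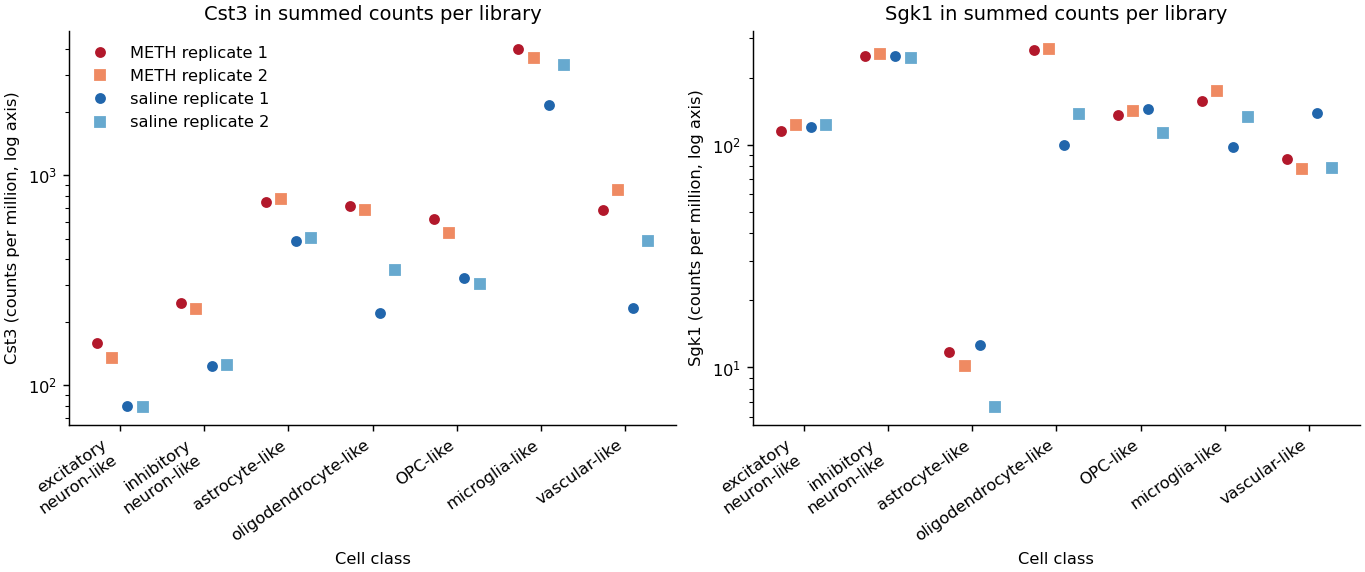
Cst3 (left) and Sgk1 (right) in CPM on a log axis, for the summed counts of each cell class and library. Cst3 lies higher in both METH libraries than in both saline libraries in every class plotted, while Sgk1 does so in oligodendrocyte-like nuclei (267 and 269 against 100 and 138) and in microglia-like nuclei (157 and 175 against 97.7 and 134).

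The glucocorticoid response list stood higher in METH oligodendrocyte-like nuclei. Of its 13 tested members 10 had positive fold changes (median log2 0.59, adjusted p = 5.21e-09). Over all genes 1 member rose, and adjusted over the list alone 3 did, namely Sgk1, Pdk4, a kinase that restrains pyruvate oxidation (1.20, SE 0.293), and Klf9, a transcription factor induced by corticosteroids (0.47, SE 0.163). The call was kept in all 15 alternatives that test a list with the preset correlation, with adjusted p from 1.74e-17 to 0.0164 and a median of 0.35 with at least 1000 genes per nucleus, and was lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation). The excess of Zbtb16 over the saline mean was 0.0149 UMIs per nucleus in METH replicate 1 and 0.38 in METH replicate 2, and that of Fkbp5 −6.18e-05 and 0.0831. Lists of other cell types also stood higher here. The astrocyte transport list had a median of 0.48 with all 14 members positive (adjusted p = 7.06e-05), and the astrocyte marker list a median of 0.71 over 5 members (adjusted p = 0.00235). Gja1, the astrocyte gap junction protein connexin 43 (0.90, SE 0.283), and Apoe, a lipid carrier made by astrocytes (0.52, SE 0.17), rose when adjusted over the transport list alone, while Slc1a2, the glutamate transporter, was at 0.75 (SE 0.451). The activated microglia list had a median of 0.52 over 11 members (adjusted p = 2.34e-06), and the microglia marker list 0.88 over 6 (adjusted p = 1.22e-05), with 3 members each past the threshold adjusted over the list alone, among them C1qa (1.29, SE 0.284), C1qb (1.37, SE 0.38) and the lysosomal protease gene Ctss (1.96, SE 0.459). None of the members of these 4 lists passed over all genes. C1qa stood at 0.0555 and 0.0764 UMIs per nucleus in METH and 0.0154 and 0.0319 in saline. The 4 calls were likewise lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). The astrocyte marker, astrocyte transport and microglia marker calls were also lost without saline replicate 2 (medians 0.34, 0.30 and 0.69), and the direction turned for the astrocyte markers with at least 200 genes per nucleus or the resolution doubled (−0.20 in both) and for the transport list with at least 1000 genes (−0.12). The transport call was lost, with medians under 0, with at least 200 genes (−0.03) or the resolution doubled (−0.0088), the astrocyte marker call without a filter on low counts (0.36), and the activated microglia call with at least 1000 genes (0.39). Over the alternatives the medians ran from 0.39 to 0.93 for the activated microglia list, from 0.06 without METH replicate 2 to 1.23 for the microglia markers, and up to 0.75 for the transport list.

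**Figure D3:**
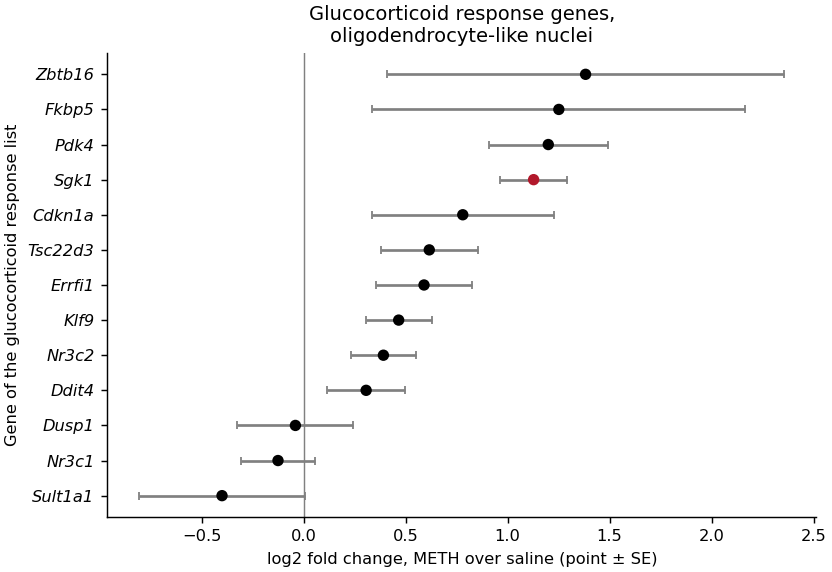
Log2 fold change, METH over saline, of the 13 tested members of the glucocorticoid response list in oligodendrocyte-like nuclei, with the standard error as a bar. Sgk1, in red, is the member past the threshold over all genes (1.13, SE 0.163), and Zbtb16 and Fkbp5 have the widest bars.

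In OPC-like nuclei 2 of 9801 genes passed, both higher in METH. Cst3 rose by 0.88 (SE 0.104, adjusted p = 9.48e-09), from 315 ± 15.2 to 576 ± 63.3 CPM (SD, n = 2), and stayed past the threshold under all 15 alternatives (highest adjusted p 5.67e-04). Mertk (ENSRNOG00000017319), a receptor kinase by which phagocytes and astrocytes take up dying cells and synapses, rose by 0.79 (SE 0.151, adjusted p = 0.0314), from 117 ± 33.9 to 210 ± 35.7 CPM. In astrocyte-like nuclei, where it was far more abundant, Mertk stood at 876, 1277, 660 and 940 CPM in METH replicates 1 and 2 and saline replicates 1 and 2. The lower genes with the smallest p were Pdzrn3, a ubiquitin ligase (−0.87, SE 0.207, adjusted p = 0.17), Tpx2, a factor of the mitotic spindle (−1.23, SE 0.342, adjusted p = 0.726), and Enpp1, an enzyme that splits extracellular nucleotides (−1.12, SE 0.317, adjusted p = 0.787). Leaving out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 gave 17, 2, 2 and 26 genes. The adjusted p of Mertk ran from 8.3e-06 to 1 over 15 alternatives and was above 0.05 in 9 of them, the fits without METH replicate 2 (1), without saline replicate 1 (0.369), not robust, by DESeq2 (1), with at least 200 or 1000 genes per nucleus, with at most 1% mitochondrial UMIs, with doublets kept and with the resolution doubled.

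The lists that stood higher in OPC-like nuclei were those of microglia. The homeostatic microglia list had a median of 0.43 over 7 members (adjusted p = 0.00222), with Mertk the 1 member past the threshold, over all genes as well as adjusted over the list alone. Mertk is also an astrocyte gene, as its levels above show. The activated microglia list had a median of 0.33 over 10 members (adjusted p = 0.00128) and the microglia marker list 0.49 over 5 (adjusted p = 0.0238). None of their members passed over all genes, and 3 and 2 rose adjusted over the list alone, among them B2m (0.58, SE 0.214), C1qb (0.92, SE 0.352) and C1qa (0.76, SE 0.293). All 3 calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). The homeostatic microglia and microglia marker calls were also lost without METH replicate 2 (medians 0.36 and 0.41) or saline replicate 2 (0.27 and 0.30). The activated microglia call was lost without a filter on low counts (0.15) or with at least 1000 genes per nucleus (0.38). Over the alternatives the medians ran from 0.20 to 0.44 for the homeostatic list, from 0.15 to 0.47 for the activated list and from 0.30 to 0.59 for the markers.

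In microglia-like nuclei none of 7452 genes passed by edgeR and none by DESeq2. The 255 at an unadjusted p under 0.05 by edgeR were a smaller share than the 0.05 expected if no gene differed. The higher genes with the smallest p were the myelin genes Mag (2.30, SE 0.576) and Mal (1.35, SE 0.359) and Ncoa3, a coactivator of nuclear receptors (0.50, SE 0.137). The lower ones were Lama2, a laminin chain of basement membranes (−2.07, SE 0.556), Ttc9c (−1.02, SE 0.32) and Olr1, a receptor for oxidised lipoprotein (−0.999, SE 0.324), all at an adjusted p of 1. Cst3 was at 0.43 (SE 0.157). By camera the myelin list (median 0.31 over 9 members, adjusted p = 0.0202) and the astrocyte transport list (0.40 over 7, adjusted p = 6.33e-04) stood higher, with 0 members past the threshold over all genes and 3 and 1 adjusted over the list alone. The bicarbonate transporter Slc4a4 was at 1.75 (SE 0.584) and Gja1 at 0.85 (SE 0.33). The activated microglia list (0.21 over 19, adjusted p = 0.0346) and the microglia markers (0.13 over 12, adjusted p = 0.0334) stood slightly higher, with Tyrobp, a signalling adaptor of microglia, at 0.45 (SE 0.235), C1qb at 0.36 (SE 0.186) and Ctss at 0.33 (SE 0.133), and 0 members past the threshold over all genes or adjusted over the list alone. All 4 calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). The myelin call was also lost without METH replicate 2 (median 0.20) or saline replicate 2 (0.07), without a filter on low counts (−0.03) or with doublets kept (0.11). It was lost with the replicate number as a block (0.28) and turned with at least 1000 genes per nucleus (−0.0692). The astrocyte transport call was lost without saline replicate 2 (0.57) or with at least 1000 genes (0.19). The activated microglia call was lost without METH replicate 1 (0.04) or saline replicate 1 (0.09), without a filter on low counts (0.26) or with doublets kept (0.17). The microglia marker call was lost without METH replicate 2 (0.09) or saline replicate 1 (0.02), with at least 200 genes (0.09), with at most 1% mitochondrial UMIs (0.11) or with equal numbers of nuclei (0.23). Over the alternatives the highest medians were 0.47 for myelin, 0.79 for astrocyte transport, 0.41 for activated microglia and 0.24 for the microglia markers. Saline replicate 1 gave 154 microglia-like nuclei, and leaving out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 gave 1, 0, 2 and 26 genes.

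In vascular-like nuclei none of 6954 genes passed by edgeR. The 197 at an unadjusted p under 0.05 were a smaller share than the 0.05 expected if no gene differed. DESeq2 called 1, Adamtsl3, a glycoprotein of the extracellular matrix (−2.50, adjusted p = 0.0469). By edgeR Adamtsl3 was at −2.45 (SE 0.368, adjusted p = 0.735), followed among the lower genes by the ether lipid enzyme Agmo (−3.04, SE 0.498) and the axon guidance factor Sema3d (−2.61, SE 0.467). The higher genes with the smallest p were Col4a4, a basement membrane collagen (1.55, SE 0.32), Omg, a glycoprotein of oligodendrocyte myelin (1.57, SE 0.398), and Sh2d3c (1.28, SE 0.347). Cst3 was at 1.08 (SE 0.387, adjusted p = 1). Leptomeningeal-like nuclei were 29.2% and 31.4% of this class in METH and 50.6% and 44.5% in saline. Endothelial-like nuclei were 44.1% and 44.6% against 37.9% and 35.7%, so the largest cluster of the class differed between the groups. Pericyte or smooth muscle-like nuclei were 26.8% and 23.9% in METH, and 11.5% and 19.8% in saline replicates 1 and 2. Fits that left out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 called 0, 8, 169 and 147 genes.

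With these proportions, 7 lists were called in vascular-like nuclei. The vascular markers had a median of 0.54 over 17 members (adjusted p = 2.50e-08), with the pericyte genes Rgs5 (1.32, SE 0.404) and Atp13a5 (1.52, SE 0.558) at the smallest p, and the ribosomal proteins a median of 0.64 over 29 (adjusted p = 7.83e-08), with Rpl10 (1.11, SE 0.357) and Rps15 (1.42, SE 0.567). The activated microglia list (0.73 over 7, adjusted p = 0.0115), the myelin list (0.44 over 9, adjusted p = 0.0144), the oligodendrocyte markers (0.38 over 8, adjusted p = 0.0295) and the mitochondrially encoded genes (0.33 over 10, adjusted p = 0.0451) also stood higher. Examples were C1qa (1.08, SE 0.429), Apoe (0.75, SE 0.351), Mobp (1.92, SE 0.599), Mbp (1.06, SE 0.46) and Mt-nd4 (0.55, SE 0.279). The astrocyte markers stood lower (median −0.12, mean −0.42 over 6 members, adjusted p = 0.0308), with Slc4a4 at −1.39 (SE 0.341) and Gja1 at −0.97 (SE 0.323). No member of the 7 lists passed over all genes, and adjusted over the list alone the 2 astrocyte markers just given fell and none of the others changed. All 7 calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). Without METH replicate 1 the calls of the astrocyte markers (median −0.05), myelin (0.38) and oligodendrocyte markers (0.13) were lost, and without METH replicate 2 those of ribosomal proteins (0.03), mitochondrial genes (0.07), myelin (0.51) and activated microglia (0.11, with the test turned). Without saline replicate 1 the calls of the vascular markers (0.07), mitochondrial genes (0.21) and activated microglia (0.54) were lost, and without saline replicate 2 those of the astrocyte markers (−0.24), myelin (0.75) and oligodendrocyte markers (0.32). With at most 1% mitochondrial UMIs the calls of activated microglia (0.35), ribosomal proteins (0.27), mitochondrial genes (0.12), myelin (0.19) and oligodendrocyte markers (0.02) were lost, and with equal numbers of nuclei those of mitochondrial genes (0.32), myelin (0.29) and oligodendrocyte markers (0.22). The astrocyte marker call was lost without a filter on low counts (−0.06), with at least 200 genes (−0.07) or with doublets kept (0.0092), the activated microglia call without a filter (0.65), and the mitochondrial call with the resolution doubled (0.31). Over the alternatives the medians ran from −0.03 to 2.06 for the vascular markers, from −0.53 to 0.0092 for the astrocyte markers, and up to 0.93 for ribosomal proteins, 0.56 for mitochondrial genes, 0.86 for oligodendrocyte markers and 1.165 for activated microglia. In the endothelial-like cluster alone, an alternative chosen after seeing the data, 5 of the 7 lists had enough members to test. None of the 5 was called. Their medians were −0.03 for the vascular markers, −0.13 for the astrocyte markers, 0.64 for myelin, 0.29 for mitochondrial genes and 0.33 for ribosomal proteins.

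**Figure D4:**
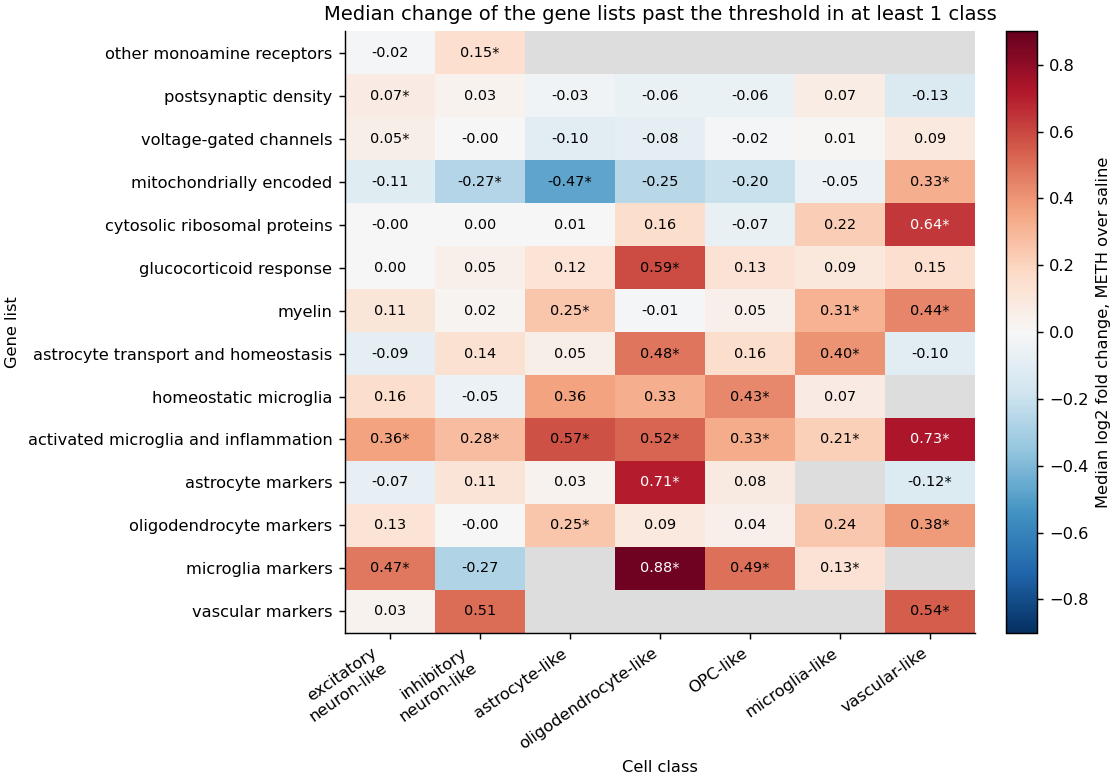
Median log2 fold change, METH over saline, of the gene lists past the threshold by camera with the preset correlation in at least 1 class (lists in rows, cell classes in columns); an asterisk marks adjusted p under 0.05, and grey marks lists with too few tested members. The activated microglia and inflammation list is marked in all 7 classes, with medians from 0.21 to 0.73, and the glucocorticoid response list in oligodendrocyte-like nuclei (0.59). All marked calls were lost by camera with an estimated correlation (lowest adjusted p 0.956). That version also called no raised list in the simulation, so the loss does not decide on the calls.

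No gene was called for a different response to METH in inhibitory than in excitatory neuron-like nuclei. Of 14936 genes, 0 passed for the class-by-treatment term by edgeR and 0 by DESeq2. The 534 at an unadjusted p under 0.05 by edgeR were a smaller share than the 0.05 expected if no gene differed. Rspo2 came closest, with a METH effect lower by 0.54 on the log2 scale in inhibitory than in excitatory neurons, a difference of −0.54 at adjusted p = 0.61. Without METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 the count of genes was 12, 0, 11 and 39.

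When all nuclei of a library were summed, so that class shares also enter, none of 16243 genes passed by edgeR. The 997 at an unadjusted p under 0.05 were here a larger share than the 0.05 expected if no gene differed. DESeq2 called 20, all higher in METH. B2m (0.81, SE 0.0896, adjusted p = 0.233), Cst3 (1.00, SE 0.123, adjusted p = 0.611) and Apoe (0.47, SE 0.0781) were the higher genes with a gene name and Fcho1, an endocytosis factor (−0.31, SE 0.0606), and Fosl1 (−0.91, SE 0.178) the lower genes with the smallest p by edgeR. The DESeq2 calls included Cst3 (1.00), B2m (0.81), C1qb (1.01), C1qa (0.90), Glul, the glutamine synthetase of astrocytes (0.70), and Tsga10ip (1.38). Leaving out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 gave 9, 0, 0 and 191 genes by edgeR.

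Over the 7 classes, 212 pairs of a class and a list were tested and camera called 30, of which 27 were higher and 3 lower in METH. With an estimated correlation 0 pairs were called (6 at an unadjusted p under 0.05, lowest adjusted p 0.956), and with fry, which asks whether the genes of a list move one way on balance, also 0 (16 at an unadjusted p under 0.05, lowest adjusted p 0.221). In the simulation neither version called a list raised by 0.5 on the log2 scale, so their 0 calls cannot decide on the 30. Fits that left out METH replicate 1, METH replicate 2, saline replicate 1 or saline replicate 2 called 52, 33, 73 and 64 pairs, of which 22, 19, 22 and 16 were among the 30.

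Of the lists tested, 20 were called in no class, among them the immediate early genes and dopamine and cAMP signalling. The lowest adjusted p was 0.091 for the immediate early genes (medians from −0.0018 to 0.26 over the classes), 0.0967 for dopamine and cAMP signalling (−0.02 to 0.10), 0.0689 for glutamate receptors (−0.11 to 0.11), 0.577 for GABA genes, 0.0689 for neuropeptide, opioid and cannabinoid genes, 0.133 for synaptic vesicle and release genes and 0.144 for synaptic adhesion. It was 0.526 for chromatin and DNA methylation, 0.434 for nuclear-encoded oxidative phosphorylation, 0.14 for heat shock, 0.562 for the unfolded protein response, 0.109 for oxidative stress, 0.143 for the circadian clock, 0.126 for cholesterol synthesis, 0.568 for reactive astrocyte genes and 0.616 for the interferon response. For markers of cell types it was 0.611 for striatal spiny neurons, 0.0894 for excitatory neurons, 0.616 for inhibitory neurons and 0.131 for OPCs. The blood list had too few tested members in every class.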

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

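The shares after thinning, the shares without each library, the fits without differentiating cells or with the endothelial-like cluster alone, and the tests in subclasses were chosen only after the results were seen. Among the genes past the threshold, 30 results gave 406 values under alternatives, of which 318 kept their direction and call, 88 kept their direction and lost the call, and 0 turned. Among the other genes followed, not past it, 94 results gave 1388 values, of which 100 passed under an alternative and 8 turned in direction, in 6 genes. The 30 list calls gave 414 values, of which 325 kept the call, 82 lost it and 7 turned, in 6 pairs. With 2 libraries per group the spread between libraries rests on few degrees of freedom. Where a value moved, the cause was not tested, except that a fit without 1 library has fewer samples.

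Without a filter on low counts, the number of genes called was 6 in excitatory and 8 in inhibitory neuron-like nuclei, 11 in astrocyte-like, 26 in oligodendrocyte-like and 23 in vascular-like nuclei, 1 in all nuclei and 9 for the class-by-treatment term. A fit that was not robust called 1 gene in excitatory neuron-like and 1 in OPC-like nuclei. With at least 1000 genes per nucleus 1 gene was called in excitatory neuron-like and 0 in oligodendrocyte-like nuclei, and with at least 200 genes 0 in oligodendrocyte-like and 1 in OPC-like nuclei. With at most 1% mitochondrial UMIs 2 genes were called in astrocyte-like and 1 in OPC-like nuclei. Keeping doublets gave 0 genes in oligodendrocyte-like and 1 in OPC-like nuclei and 49 list pairs, and doubling the resolution 0 and 1 genes in these classes. Equal nuclei per library gave 1 gene each in excitatory neuron-like, inhibitory neuron-like and oligodendrocyte-like nuclei and 4 in astrocyte-like nuclei. DESeq2 called 3 genes in excitatory neuron-like nuclei, the 2 called by edgeR and Tsga10ip, 1 gene each in inhibitory neuron-like, OPC-like and vascular-like nuclei and 20 in all nuclei. With an estimated correlation, and with fry, 0 list pairs were called, against 30 by camera with the preset correlation. Neither called the simulated raised list in any class either.

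With the replicate number as a block, 8 genes were called in excitatory and 11 in inhibitory neuron-like nuclei, 22 in astrocyte-like, 44 in oligodendrocyte-like, 7 in OPC-like, 2 in microglia-like and 0 in vascular-like nuclei, 19 in all nuclei, and 46 list pairs. Of the 30 list calls the block ended 1, that of the myelin list in microglia-like nuclei (median 0.28, adjusted p = 0.0875). In the L5/6 NP-like subclass the block ended all 6 calls, with adjusted p from 0.0632 to 0.512. Over the genes of a class, the differences between replicates 1 and 2 in METH and in saline correlated at −0.0204 in excitatory and −0.0416 in inhibitory neuron-like nuclei, 0.134 in astrocyte-like, 0.125 in oligodendrocyte-like, 0.0453 in OPC-like, 0.0738 in microglia-like and 0.192 in vascular-like nuclei and 0.179 in all nuclei. With 2 pairs, and no label that ties equal numbers together, the samples share only a number. The block was not run for the class-by-treatment term, where the library is already a block.

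Leaving out each library in turn gave from 0 to 63 genes in excitatory and 1 to 34 in inhibitory neuron-like nuclei, 2 to 128 in astrocyte-like, 3 to 148 in oligodendrocyte-like, 2 to 26 in OPC-like, 0 to 26 in microglia-like and 0 to 169 in vascular-like nuclei, 0 to 191 in all nuclei, 0 to 39 for the class-by-treatment term, and 33 to 73 list pairs. Over those fits the number of genes moved by more than 1.5 times in every class.

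The METH minus saline difference in the share of excitatory neuron-like nuclei was −10.4 percentage points, and −3.15 after thinning to the depth of saline replicate 1. For inhibitory neuron-like nuclei it was 0.115, and 2.20 after thinning and 2.30 with at least 1000 genes. For oligodendrocyte-like nuclei it was 6.25, and 1.09 and 1.85 under these settings, and for microglia-like nuclei 2.63, and 0.150 and 0.959. For astrocyte-like nuclei it was 3.70, and 2.92 and 5.96 under the same settings, and for OPC-like nuclei 2.47, and 2.10 and 3.36. For vascular-like nuclei it was −0.285, and −0.532 after thinning, −0.00483 with at least 200 genes, −0.125 with doublets kept and −0.265 with at least 1000 genes, a setting that left 25 vascular-like nuclei in METH replicate 1, so that no gene test of the class was run there.

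Some directions turned. Leaving out each library in turn, the median log2 fold change in inhibitory neuron-like nuclei ran from −0.71 to 0.0114 for the mitochondrially encoded list and from 0.0066 to 0.279 for the other monoamine receptors, and from 0.11 to 1.165 for the activated microglia list in vascular-like nuclei, and each test turned without METH replicate 2. With at least 1000 genes per nucleus the medians were −0.0692 for the myelin list in microglia-like nuclei and −0.12 for the astrocyte transport list in oligodendrocyte-like nuclei. The astrocyte marker list in oligodendrocyte-like nuclei was at −0.20 with at least 200 genes and −0.20 with the resolution doubled. Over the same fits Npas4 in excitatory neuron-like nuclei, log2, ran from −0.18 without METH replicate 2 to 0.42, and Drd2 in excitatory neuron-like nuclei, log2, from −0.11 without METH replicate 1 to 0.39. In oligodendrocyte-like nuclei Gja1 was at −0.24 with at least 1000 genes, while for Slc1a2 in oligodendrocyte-like nuclei, log2 was −1.78 with at least 200 genes and −1.82 with the resolution doubled. For Mag in microglia-like nuclei, log2 was −0.36 with at least 1000 genes and −0.0011 with doublets kept, and Olr1 at 0.40 with at least 1000 genes.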

Other observations

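The tests in subclasses, those of doublets and of RNA inside nuclei for Cst3, those of free RNA and of differentiating cells for the glucocorticoid genes, and that of doublets in saline replicate 1 were chosen only after the results were seen. So was the use of the fit without saline replicate 1 to weigh an explanation, while that fit, the glucocorticoid list and its camera test were fixed before. Within the excitatory neuron-like class, the L5/6 NP-like cluster (near-projecting neurons of the deep layers; 212, 125, 322 and 174 nuclei in METH replicates 1 and 2 and saline replicates 1 and 2) had 6 genes called. Besides Cst3 (log2 0.87), the receptor kinase gene Alk (1.32, SE 0.249, adjusted p = 0.0116 by edgeR) and the receptor phosphatase gene Ptprk (0.80, SE 0.165) rose. The axon guidance gene Sema3d (−0.69, SE 0.13), Asb15 (−1.32, SE 0.275) and Tnfrsf19 (−1.26, SE 0.239) fell. Over 13 alternatives the adjusted p ran from 5.84e-06 to 0.725 for Alk, from 0.00479 to 1 for Ptprk, from 0.00414 to 0.725 for Sema3d, from 5.12e-04 to 1 for Asb15 and from 3e-12 to 1 for Tnfrsf19. The calls of Alk and Sema3d were lost without METH replicate 1 or saline replicate 2, those of Ptprk and Asb15 without METH replicate 2 or saline replicate 2, and that of Tnfrsf19 without METH replicate 1 (log2 −0.68). A fit that was not robust kept 3 of the 6 calls and lost those of Alk, Ptprk and Asb15. The replicate number as a block ended all 6, that of Cst3 among them. With doublets kept all but that of Cst3 were lost, Ptprk then standing at 0.30 (SE 0.323). The calls of Ptprk and Tnfrsf19 were lost with at least 1000 genes, that of Tnfrsf19 with at most 1% mitochondrial UMIs, and those of Ptprk and Asb15 with the resolution doubled. Whether these effects differ from those in other subclasses was not tested.

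Among interneurons, Rspo2 fell in Pvalb-like nuclei (−0.73, SE 0.131, adjusted p = 0.0109), while Mybpc1 rose there (0.59, SE 0.111, adjusted p = 0.0144) and in Vip-like nuclei (1.85, SE 0.289, adjusted p = 0.00407). In Vip-like nuclei Mybpc1 stood at 67.9 and 71.4 CPM in METH against 11.8 and 25.8 in saline. Over 13 alternatives the adjusted p ran from 8.33e-06 to 0.332 for Rspo2 and from 5e-04 to 0.128 for Mybpc1 in Pvalb-like nuclei, both above 0.05 without saline replicate 2 and in a fit that was not robust (0.0666 each), and from 2.06e-07 to 0.554 for Mybpc1 in Vip-like nuclei, above 0.05 without saline replicate 1. In mature oligodendrocyte-like nuclei Sgk1 (1.17, SE 0.164, adjusted p = 0.00365) and Cst3 (1.26, SE 0.173, adjusted p = 0.0192) rose. Of 12 alternatives, 2 ended the call of Sgk1, at least 200 genes (adjusted p = 0.365) and the resolution doubled (0.0801), and 1 that of Cst3, the resolution doubled (0.496). At least 1000 genes left 44 such nuclei in saline replicate 1 and was not run. In the differentiating cluster Agbl1 (1.63, SE 0.32) and Tns1, a focal adhesion gene (1.51, SE 0.297), rose at an adjusted p of 0.0483. Of 12 alternatives, 7 ended the call of Agbl1 and 8 that of Tns1, with adjusted p up to 0.363 and 0.778. Both were lost with RLE size factors (0.0631 each), in a fit that was not robust (0.162 each), with at most 1% mitochondrial UMIs (0.0765 each), with doublets kept, with the resolution doubled and without METH replicate 2, that of Agbl1 also without saline replicate 2 and that of Tns1 without METH replicate 1 or saline replicate 1.

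Cst3 was called in neuron-like, oligodendrocyte-like and OPC-like nuclei alike. Leftover doublets with microglia-like nuclei would bring other microglia markers along, but these reached at most 0.116 of their ratio to Cst3 in microglia-like nuclei in the METH libraries, and 0.17 and 0.155 in the saline libraries. Free RNA in the droplets is consistent with the data: between the shallowest and the deepest excitatory neuron-like nuclei, Cst3 grew by at most 0.239 of the log ratio of all UMIs, against at least 0.68 for the neuronal gene Slc17a7. A rise of equal fold inside the nuclei of every class was weighed against saline replicate 2 alone. There the METH excess in microglia-like nuclei was at most 0.169 of that at the excitatory neuron-like fold (95% bootstrap interval up to 0.334). In astrocyte-like nuclei it was 0.41 and 0.801. The bootstrap resampled nuclei, so its interval leaves out the spread between libraries. Microglia-like Cst3 stood at 2156 and 3356 CPM in saline replicates 1 and 2, against 3988 and 3628 in METH replicates 1 and 2. With saline libraries this far apart, the comparison cannot decide on a rise of equal fold. A rise inside the nuclei, of equal or unequal fold or in some classes only, cannot be told apart from free RNA. The excess of the METH mean over saline replicate 2 was 0.403 UMIs per excitatory neuron-like nucleus and 0.43 per OPC-like nucleus, a ratio of 0.938. But saline replicate 2 itself held like amounts in this pair of classes, 0.566 and 0.531. In astrocyte-like and microglia-like nuclei, where saline replicate 2 held 0.89 and 3.37, the excess was 0.389 and 0.366. It was 0.438, 0.439 and 0.429 in inhibitory neuron-like, oligodendrocyte-like and vascular-like nuclei. Free RNA that reaches every class alike would give such a like excess, but these values rest on saline replicate 2 alone. Whether METH or the preparation of the libraries set the amount of free Cst3 RNA was not tested.

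The glucocorticoid response list was called higher in METH oligodendrocyte-like nuclei, with 10 of 13 members positive and Sgk1 the member past the threshold over all genes, a call lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation). The median of the list stayed at 0.558 with differentiating cells left out and at 0.434 without saline replicate 1, which argues against either as the whole cause. For Sgk1, free RNA could account for at most 0.0923 of the excess over the mean of both saline libraries, judged by its lowest level in any other class. The excess was taken in UMIs per nucleus, with no adjustment for depth. Sgk1 stood at 0.345 and 0.393 in METH, at 0.102 in saline replicate 1, the shallower library, and at 0.203 in saline replicate 2. For the other members this bound was 1.05 times the excess in 1 METH library and 0.443 in the other, so free RNA and a rise inside the nuclei cannot be told apart for them; the list was first tested whole and then split. An effect of METH on Sgk1 in oligodendrocytes stays a hypothesis, found and tested on the same data.

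Saline replicate 1 held few microglia-like and oligodendrocyte-like nuclei and most of the nuclei of the unnamed cluster led by Cga. Loss of shallow nuclei below the barcode minimum is consistent with the shares: saline replicate 2 thinned to the depth of saline replicate 1 held 0.803% microglia-like nuclei, against 1.05% in saline replicate 1. Thinning left OPC-like nuclei at 8.09% in saline replicate 2, against 4.66%, which it does not account for. Whether the unnamed cluster holds doublets stays open, since the values point both ways: its median in this library was 1043 UMIs (95% bootstrap interval 1014 to 1072), against 1963 in the library, but its median doublet score was 0.308, against 0.119, and with doublets kept a like cluster held 3001 nuclei of this library, against 1511. No biological explanation was tested.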
